A study of Sus scrofa with 12 samples.

How the data were processed

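Total RNA was extracted with Trizol from the longissimus dorsi of Meishan pigs, and biotin-labelled cRNA was hybridised to Affymetrix porcine arrays, 1 array per sample, per the labels' protocols. The labels give 4 stages of 3 samples, described as biological replicates, and state that fetuses of one female were treated as 1 individual. They give no sex, litter after birth or hybridization date. The deposited values are intensities on a linear scale, 1 per probe set and array, and GCOS 1.4 is the software in the submitters' processing notes. The summary method, the background correction and the scaling target are not given in the sources used here. Array medians lay between 49.1 and 52.6, a 1.07-fold range, so no further normalization was applied. Detection calls and scanner images were not used here.

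The table held 24123 probe sets. The 124 control probe sets were set aside for quality measures, which left 23999. Values were transformed as log2(value + 21), where 21 is the 25th percentile of all values. Probe sets above the 40th percentile of their own array on at least 3 arrays were kept, which were 16166 (67.4%). Gene symbols came from a 2016 platform annotation, which gave 1 symbol for 10069 probe sets and several for 198. It did not list 13732, which are unnamed here and not without a gene. Through Entrez identifiers 9961 were found in the RefSeq gene table, and 0 symbols changed. Symbols numbered 6765, of which 405 were locus or clone names. Where a gene had several kept probe sets, the one with the highest mean over the 12 arrays stood for it, which gave 5765 genes.

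All 12 arrays entered one limma fit with 1 mean per stage and a variance trend on mean log2 value (8 residual and 4.26 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the 16166 probe sets and calls at an adjusted p under 0.05. The comparisons were the overall F test, the 3 adjacent steps, and the probe sets called in opposite directions at the first and second step. The 23 gene lists had 681 members, of which 480 matched a symbol and 459 were measured after the filter. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with the correlation estimated per list, and with fry. Some genes are in more than 1 list. Stage values are means with SD over 3 arrays, and log2 changes carry the SE of the fit. The number of arrays limits the precision.

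The rule for naming genes was fixed before the data were examined, and FNTA, EVL, UBA3, FBXO32 and AMY2 were added after their values were seen. The rule takes the 10 genes with the largest called rises and falls per step whose arrays do not overlap and whose higher mean reaches the median, up to 4 called members per list and step, list members called against their list, 28 fixed genes, of which 17 were measured, 8 genes for each transient course, and the 5 smallest overall p values. In passing, 3 locus names were skipped. The comparisons, the lists and most alternatives were fixed at the same time. The contrasts of 60 and 120 days with the fetus and of 120 with 3 days were also looked at afterwards. Of these, 120 against 3 days is reported among the other observations, with the same rule. Leaving out both arrays with a shared deviation, and centring on the hybridization controls, were chosen after seeing the data.

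The fit was tested on simulated data with independent normal noise, 1 spread per probe set for all stages, and 100 probe sets changed at each size. It recovered 64%, 66% and 63% of 2-fold changes and 100%, 97% and 98% of 4-fold changes in the 3 adjacent steps, with 9, 9 and 7 false calls among 16166. In a simulation of 5765 genes at the first step, drawn independently of each other, camera recovered the changed list and called 1 of 22 others. The estimated correlation within the measured ribosomal list was 0.751, so the simulation does not show how camera behaves on correlated lists. Alternatives were pseudocounts of 1 and 51, no filter and a filter at the 60th percentile, quantile normalization, median centring, other variance models, array weights, only the 6 arrays compared, the replicate number as a block, 1 probe set per gene, a 2-fold minimum, other list tests, and leaving out each array in turn. Software was R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.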

Results

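Transcript abundance was measured in the longissimus dorsi, the long muscle of the back, of Meishan pigs, a Chinese breed. The stages were 65 days post coitus (dpc), in the fetus, and 3, 60 and 120 days after birth. Each stage had 3 arrays, 12 in all, and the study asked how expression across the genome changes as this muscle develops. For the fetal stage, the fetuses of one sow were handled as 1 individual. The median intensity per array ranged from 49.1 to 52.6, and the highest probe set on an array from 9539 to 12737. Arrays of one stage correlated with r from 0.905 to 0.985 across probe sets, and arrays of different stages with r from 0.714 to 0.975. Probe sets are not independent replicates. The first principal component held 55.0% of the variance and placed the 3 fetal arrays between -88.4 and -65.6 and the 9 arrays after birth between 12.5 and 39.1. Fetal replicate 2 and 60 days replicate 1 were the outermost arrays on the negative side of the second component, at -21.5 and -36.8.

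**Figure D1:**
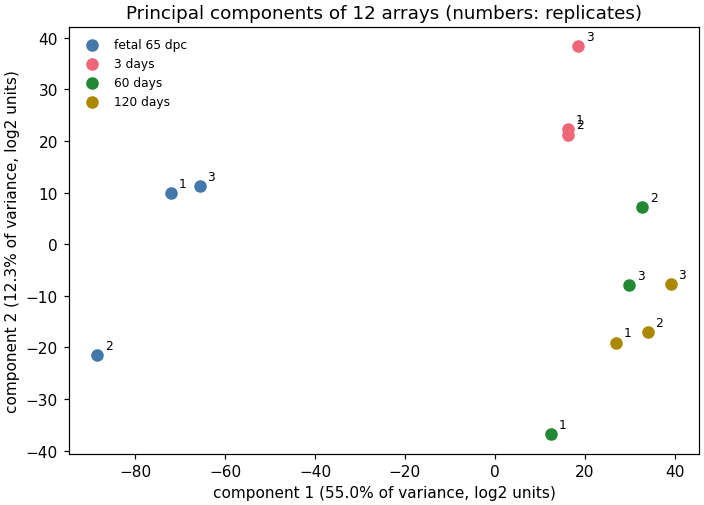
Principal components 1 (horizontal axis, 55.0% of variance) and 2 (vertical axis, 12.3% of variance) of the log2 values of the 12 arrays. Each point is 1 array, coloured by stage and numbered by replicate. The fetal arrays lie at -65.6 or below on component 1 and all arrays after birth at 12.5 or above.

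Control probe sets give a view of RNA and array quality by stage. The ratio of the 3-prime to the 5-prime probe set of actin was 2.45 ± 0.168 (SD, n = 3) in the fetus, 3.61 ± 1.06 at 3 days, 5.10 ± 1.17 at 60 days and 5.08 ± 0.896 at 120 days. One GAPDH pair gave 1.46 ± 0.0168 in the fetus and 1.01 ± 0.0207 at 3 days, with both its probe sets between 9128 and 12078 after birth, close to the highest intensities on these arrays. The 2 other GAPDH pairs went the other way, from 0.765 ± 0.0584 to 1.03 ± 0.0198 and from 0.858 ± 0.0663 to 0.999 ± 0.0276. The EF1A pair gave 0.929 ± 0.0184, 1.0035 ± 0.0826, 1.03 ± 0.0444 and 1.12 ± 0.0161 in stage order. The bioB hybridization control averaged 181 ± 25.4 in the fetus and 265 ± 33.8 at 3 days. Among 21 exact two-sided permutation tests of such values between adjacent stages, the smallest p was 0.1, which is the smallest that 3 arrays against 3 allow, and no adjusted p was under 0.42.

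Across the 4 stages, 7588 of 16166 probe sets (46.9%) differed by limma's moderated F test. Of these, 48.4% had their highest mean in the fetus and 24.2% at 120 days. The lowest mean was in the fetus for 44.4% and at 120 days for 27.9%. The 5 named genes with the smallest adjusted p were MYH2 (a fast myosin heavy chain), TMOD4 (a tropomodulin that caps thin filaments in muscle), FMO1 (a flavin monooxygenase), TMEM158 and MYL4 (a light chain of embryonic and atrial myosin). MYL4 averaged 2675 ± 581 (SD, n = 3) in the fetus and 53.2 ± 8.71 at 120 days. FMO1 averaged 8.10 ± 0.391, 127 ± 31.2, 404 ± 46.7 and 214 ± 38.0 in stage order, and TMEM158 fell from 406 ± 62.2 in the fetus to 48.8 ± 4.44 at 3 days.

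The comparison of 3 days after birth with the fetus spans birth, and across it genes of adult fast fibres rose while some fetal contractile genes fell. MYH2 rose from 205 ± 34.6 to 5828 ± 1245 (SD, n = 3), a log2 change of 4.69 ± 0.18 (SE, adjusted p = 5.70e-08). MYL4 went the other way, with a log2 change of -5.08 ± 0.22 (adjusted p = 7.00e-08), and TNNT2, the cardiac and fetal troponin T, fell from 875 ± 252 to 46.5 ± 27.1 (log2 change -3.78 ± 0.30, adjusted p = 5.58e-06). Of 8 measured fast-fibre genes 7 rose, and 8 did when adjusted over the list alone, among them ATP2A1, the calcium pump of fast fibres (2.53), and TNNT3, fast troponin T (0.85). Their median log2 change was 0.85 (camera adjusted p = 1.55e-04, and adjusted p = 0.242 with an estimated correlation). All 5 measured genes of calcium handling rose, also when adjusted over the list alone, with RYR1, the calcium release channel, at 1.04. The median was 1.06 (camera adjusted p = 0.00256, and adjusted p = 0.127 with an estimated correlation). Among 5 developmental contractile and junction isoforms 2 fell and 3 did not pass the test, and adjusted over the list alone 2 fell and 1 rose. Their median was -0.57 (camera adjusted p = 0.0298, and adjusted p = 0.141 with an estimated correlation). The slow-fibre list did not pass (median 0.40, camera adjusted p = 0.154): of 10 genes 3 rose (MYL3 2.47, TNNT1 0.75, MYL2 0.66) and TPM3 fell (-1.04), with the same 3 and 1 adjusted over the list alone. MYH7, the slow myosin heavy chain, had a change of 0.51 ± 0.25 and TNNI1, slow troponin I, one of 0.048 ± 0.17, and neither passed the test.

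Lists of energy metabolism were higher at 3 days than in the fetus. Of 53 measured genes of oxidative phosphorylation 49 rose and none fell, and 51 rose when adjusted over the list alone. COX7A1, the muscle form of a cytochrome oxidase subunit, rose from 192 ± 121 to 2422 ± 98.1 (log2 change 3.71 ± 0.42, adjusted p = 6.02e-05), and ATP5G1 and NDUFS7 by 2.48 and 2.43. The list's median was 1.59 (camera adjusted p = 2.57e-15, and adjusted p = 0.242 with an estimated correlation). In the tricarboxylic acid cycle 20 of 21 genes rose, and 21 adjusted over the list alone, led by IDH3A (2.18) and PDHA1 (2.17), with a median of 1.50 (camera adjusted p = 5.49e-10, and adjusted p = 0.127 with an estimated correlation). In fatty acid uptake and oxidation 19 of 24 rose, and 20 adjusted over the list alone, with a median of 1.68 (camera adjusted p = 1.96e-09, and adjusted p = 0.0539 with an estimated correlation). Its members included PDK4, a kinase that inhibits pyruvate dehydrogenase, which rose from 245 ± 213 to 3641 ± 1339 (adjusted p = 6.47e-05), CPT1B, the muscle carnitine palmitoyltransferase, at 2.79 and FABP3, a fatty acid binding protein, at 2.70. In glycolysis and glycogen 14 of 21 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 1.27e-04, and adjusted p = 0.212 with an estimated correlation). PYGM, muscle glycogen phosphorylase, rose by 2.30 and PFKM, muscle phosphofructokinase, by 2.14. The member that fell was HK1 (-1.59), the hexokinase found in most tissues. PPARGC1A, a coactivator of mitochondrial genes, had a change of 0.37 ± 0.61 and did not pass the test.

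Lists of stress response and protein turnover were also called higher at this step. Of 21 immediate-early and heat-shock genes 10 rose and none fell, and 11 rose when adjusted over the list alone. BAG3 (2.83), HSPB7 (2.67) and CRYAB (2.35), a co-chaperone and small heat-shock proteins of muscle, were among them. The median was 0.63 (camera adjusted p = 0.0498, and adjusted p = 0.272 with an estimated correlation). This call was lost without fetal replicate 1 (adjusted p = 0.0900), fetal replicate 3 (0.0658), 3 days replicate 1 (0.103), 60 days replicate 2 (0.0506) and 120 days replicate 3 (0.0523), and in 13 of 27 alternatives in all. Of 36 genes of the proteasome and muscle protein breakdown 9 rose and 1 fell, or 8 and 1 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 0.0137, and adjusted p = 0.660 with an estimated correlation), and this list was not called without 3 days replicate 3 (adjusted p = 0.0775). FOXO1, a transcription factor of muscle atrophy genes, rose by 1.23, and CAST, the inhibitor of calpain proteases, fell (-1.27). Other genes with large rises were ANKRD1, a titin-associated ankyrin repeat protein (3.99 ± 0.62), KLF9, a zinc finger factor (3.59 ± 0.25), CKMT2, mitochondrial creatine kinase of muscle (3.49 ± 0.35), MCRIP2 (3.26 ± 0.37) and TMOD4 (3.89 ± 0.23).

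Matrix, cell cycle and fetal growth genes were lower at 3 days. Of 32 extracellular matrix genes 22 fell and 2 rose, with the same counts adjusted over the list alone. VCAN, the proteoglycan versican, fell from 1169 ± 382 to 63.6 ± 11.6 (log2 change -3.77 ± 0.35, adjusted p = 1.46e-05), and THBS2, a thrombospondin, changed by -3.81 and POSTN, periostin, by -3.52. Their median was -1.21 (camera adjusted p = 4.32e-08, and adjusted p = 0.212 with an estimated correlation). The members that rose were TIMP3 (0.59), an inhibitor of metalloproteinases, and COL5A2 (0.52), a fibrillar collagen chain. Both probe sets were dim. TIMP3 was at 30.2 to 51.3 on the fetal arrays and 58.9 to 89.5 at 3 days, and COL5A2 at 46.3 to 63.8 and 79.0 to 94.6. With the arrays centred on the hybridization controls both calls were lost (limma adjusted p = 0.277 and 0.382). The call of TIMP3 was lost without fetal replicate 1 (adjusted p = 0.0682) or 3 days replicate 1 (0.0745), and that of COL5A2 without fetal replicate 2 (0.0846), 3 days replicate 1 (0.0608) or 3 days replicate 2 (0.0749). COL3A1 had a change of 0.14 ± 0.23 that did not pass. Its probe set was dim, at 41.4 to 55.1 on the fetal arrays and 42.6 to 77.4 at 3 days. The array medians were 49.1 to 52.6. At this low intensity the result does not exclude a change of the gene. Of 34 cell cycle genes 19 fell and 3 rose, or 20 and 3 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 4.36e-05, and adjusted p = 0.127 with an estimated correlation). TOP2A, topoisomerase II of dividing cells, changed by -2.43 ± 0.44 (adjusted p = 0.00111), and MCM2, of the replication helicase, by -2.11. AURKB (0.83) and PLK1 (0.53), mitotic kinases, and FEN1 (0.64), a nuclease of DNA replication, rose. With the arrays centred on the hybridization controls these 3 calls were lost (limma adjusted p = 0.0526, 0.308 and 0.0666). Of 11 imprinted and fetal growth genes 8 fell and none rose, with the same counts adjusted over the list alone, and of the 12 lists called at this step this 1 kept its call with an estimated correlation. The median was -1.57 (camera adjusted p = 7.87e-05, and adjusted p = 0.0479 with an estimated correlation). PEG10, a paternally expressed gene, fell from 3319 ± 653 to 327 ± 91.0, and MEG3, a maternally expressed long RNA, changed by -2.10 and PLAGL1 by -1.93. IGF2, a fetal growth factor, changed by -0.94 ± 0.29 (adjusted p = 0.0227). Of its 10 other probe sets 3 were called lower and 2 higher, and its own call was lost without fetal replicate 2 (adjusted p = 0.0827) or 3 days replicate 1 (adjusted p = 0.0970). Other large falls were those of SPP1, osteopontin (-4.55 ± 0.35), FNDC1 (-4.09 ± 0.46), EGFL6 (-3.48 ± 0.24) and FIBIN (-3.58 ± 0.28), a gene whose 1 other probe set was called higher.

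Regulators of muscle formation and markers of other cell types gave mixed results at this step. Of 12 myogenic regulators 4 fell and none rose, or 3 adjusted over the list alone (median -0.31, camera adjusted p = 0.154). MSTN, myostatin, an inhibitor of muscle growth, fell from 686 ± 397 to 53.5 ± 34.5 (log2 change -3.24 ± 0.59), and MYF5, a myogenic factor, changed by -2.47 and FST, follistatin, by -1.43. MYOD1 had a change of -0.64 ± 0.34 and MYF6 one of 1.13 ± 0.51, and neither passed. The remaining lists were not called (camera adjusted p from 0.0994 to 0.869). In adipocyte and lipid storage 7 of 18 rose and 1 fell, or 9 and 1 adjusted over the list alone, with CFD, adipsin, at 2.39. In cartilage and bone 4 of 8 fell and none rose, also adjusted over the list alone. In nerve and Schwann cells 2 of 6 rose and 3 fell, in smooth muscle and pericytes 1 of 8 rose and 2 fell, in endothelial cells 1 of 15 rose and 2 fell, and in erythroid cells 2 of 6 rose and 1 fell, each with the same counts adjusted over the list alone. The receptor for transferrin, TFRC, in the erythroid list, rose from 40.8 ± 3.74 to 557 ± 169 and RGS5, a pericyte marker, by 2.08. In the same 2 lists HBB, a haemoglobin chain, and PDGFRB, also a pericyte marker, were called lower. HBB read 491, 577 and 251 on the fetal arrays and 228, 167 and 205 at 3 days. Its call held in 9 of 12 fits with 1 array left out. PDGFRB read 344, 571 and 327, then 205, 187 and 239. In interferon response and antigen presentation 2 of 23 rose and 1 fell, or 2 and 0 adjusted over the list alone. The member that fell, GBP2, read 48.0, 68.6 and 1001 on the fetal arrays. Its call held in 3 of 12 fits with 1 array left out (limma adjusted p up to 0.104). In immune cells 1 of 22 rose, and 0 by limma adjusted over the list alone. In cytoplasmic ribosomal proteins 1 of 60 rose and 2 fell, and 0 by limma adjusted over the list alone, with 4 members of that list at an unadjusted p under 0.05 and 3 of the immune list. The median, the mean and the direction of the test differed in sign for the endothelial (0.18, mean -0.088, test lower), smooth muscle (0.045, mean 0.13, test lower), ribosomal (0.0062, mean 0.015, test lower) and erythroid (-0.13, mean 0.27, test higher) lists. The immune list lay 1.66 above its stage mean on fetal replicate 3, and without that array its median turned from -0.21 to 0.50.

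**Figure D2:**
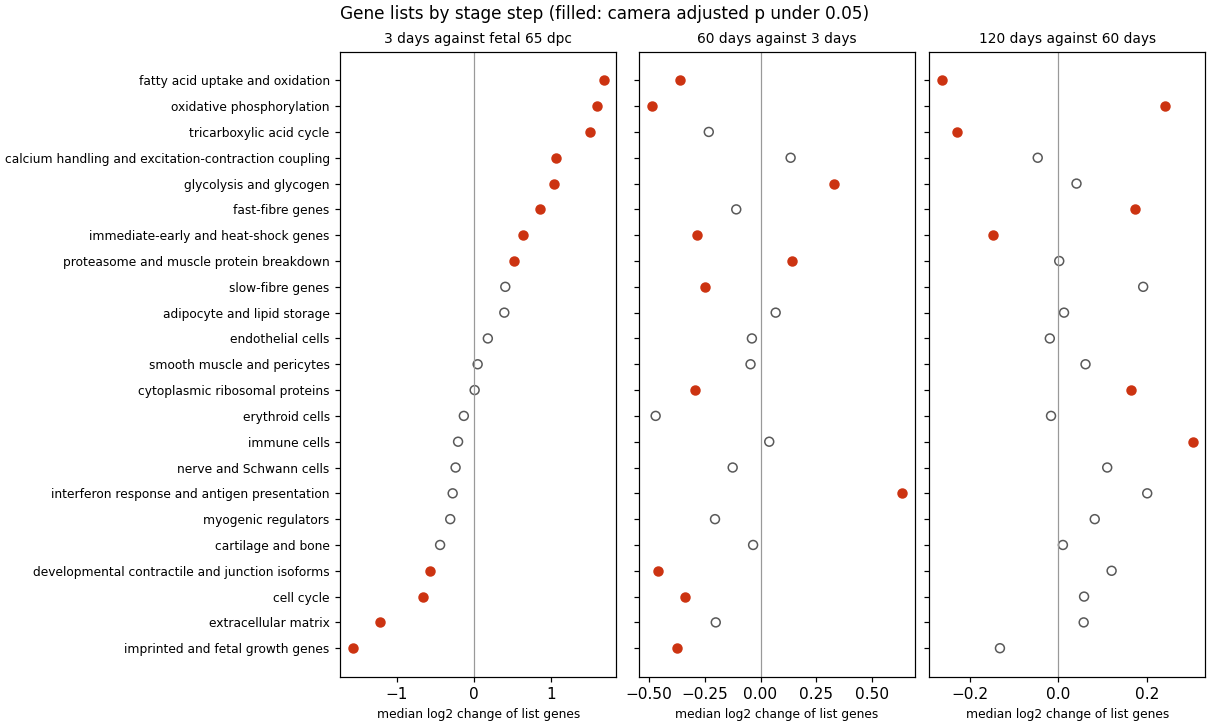
Median log2 change of the measured genes of each of the 23 gene lists (vertical axis) in 3 days against fetal, 60 days against 3 days and 120 days against 60 days (horizontal axes, log2 units, with a different scale in each panel). Filled points are lists with a camera adjusted p under 0.05, open points the others. Between the fetus and 3 days the medians run from -1.57 for imprinted and fetal growth genes to 1.68 for fatty acid uptake and oxidation.

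In total 6945 probe sets passed limma's test between the fetus and 3 days, 3286 higher and 3659 lower at 3 days, of which 2545 changed at least 2-fold. At an unadjusted p under 0.05 there were 8289, against 808 that chance alone gives, and the 3 arrays of one stage did not overlap those of the other for 53.0% of probe sets, against 10% by chance. Directions are relative to the overall level of each array. With the arrays centred on the hybridization controls instead, the median of all probe sets lay at -0.30 on the log2 scale and the split became 1179 higher and 5384 lower, or 18.0% higher in place of 47.3%. Of 113 named calls 18 were then lost (TPM1, MYL2, CKM, AURKB, FEN1, PLK1, TIMP3, COL5A2, PSMB3, FABP4, LEP, IFIT2, MX2, JCHAIN, EEF1A1, NEFL, SOX10 and FLT1), MYOD1 was called lower (adjusted p = 0.0290) and the fast-fibre list had 4 genes higher in place of 7. The oxidative phosphorylation list had 45 of its genes higher, the tricarboxylic acid cycle 19, the fatty acid list 17 and calcium handling 5. Glycolysis and glycogen had 13 higher and 1 lower, the heat-shock list 8 and 2 (10 and 0 before), the proteasome list 3 and 1 (9 and 1 before), the adipocyte list 3 and 1 (7 and 1 before), the slow-fibre list 2 and 1, erythroid cells 2 and 2, and smooth muscle 1 and 2. In that centring 0 cell cycle, matrix, ribosomal and endothelial genes were higher by limma, and 22, 23, 7 and 6 were lower. Also with 0 higher by limma, 9 imprinted genes, 5 myogenic regulators, 4 nerve genes (2 higher and 3 lower before), 4 cartilage genes, 2 developmental isoforms, 1 interferon and 1 immune gene were lower. Leaving out any single array kept the call of 91 of 113 named genes.

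Between 3 and 60 days the largest falls among named genes were those of ACTC1 and CASQ2, a contractile and a calcium-storage gene known from heart. ACTC1, cardiac alpha-actin, fell from 5117 ± 2038 (SD, n = 3) to 646 ± 325, a log2 change of -3.01 ± 0.40 (SE, adjusted p = 0.00506). CASQ2, the calsequestrin of heart and slow muscle, fell from 913 ± 301 to 109 ± 80.1 (log2 change -2.97 ± 0.40, adjusted p = 0.00549). IGF2 fell from 1355 ± 519 to 299.7 ± 25.8 (log2 change -2.02 ± 0.29, adjusted p = 0.00681), and 7 of its 10 other probe sets were called lower and none higher. ZNF385D, a zinc finger gene (-2.42 ± 0.20), and ACOT7, an acyl-CoA thioesterase (-1.98 ± 0.20), fell too. CAMK2G, a calmodulin-dependent kinase, rose by 1.66 ± 0.27 and FMO1 by 1.53 ± 0.18. These calls and that of STAMBPL1 at this step (0.98) were the 8 of 37 named calls that held without any single array. The 29 others included the rises of MSS51, a muscle zinc finger gene (2.81), BPGM, bisphosphoglycerate mutase (2.23), ALDH1A1, a retinaldehyde dehydrogenase (1.79), ME1, malic enzyme (1.76), and CAPN3, the calpain of muscle (1.12), and the falls of TFRC (-2.84), GLRX (-2.27), NME1 (-2.04), PEG10 (-1.80) and CPT1B (-1.54). Of the 37, 26 lost the call without 3 days replicate 1, 24 without 3 days replicate 2 and 26 without 60 days replicate 1, with adjusted p up to 0.164. MYH2, MYH7, CKM, MSTN and PPARGC1A had changes of 0.42 ± 0.18, 0.037 ± 0.25, 0.0024 ± 0.18, 0.97 ± 0.59 and 1.50 ± 0.61, and none of these passed the test.

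Camera at the preset correlation called 11 lists between 3 and 60 days, 3 higher and 8 lower, and few members passed on their own. With an estimated correlation 0 lists were called, and fry called 5. In cell cycle 1 of 34 genes fell (CCND2, a D-type cyclin, -1.25), and 6 did when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 5.91e-06, and adjusted p = 0.196 with an estimated correlation). In fatty acid uptake and oxidation 2 of 24 fell (CPT1B, and ECI1 at -1.05), or 5 with 1 rise adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00881, and adjusted p = 0.454 with an estimated correlation). In imprinted and fetal growth genes 2 of 11 fell, IGF2 and PEG10, or 4 with 1 rise adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0357, and adjusted p = 0.251 with an estimated correlation). Of 5 developmental isoforms 1 fell, ACTC1, or 2 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.00427, and adjusted p = 0.196 with an estimated correlation). Of 10 slow-fibre genes 1 fell, CASQ2, also adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0229, and adjusted p = 0.454 with an estimated correlation). Glycolysis and glycogen had a median of 0.33 (camera adjusted p = 0.00427, and adjusted p = 0.454 with an estimated correlation), with 2 genes higher and 1 lower adjusted over the list alone, and interferon response and antigen presentation one of 0.64 (camera adjusted p = 0.00665, and adjusted p = 0.726 with an estimated correlation), with 2 higher adjusted over the list alone. By limma 0 members of either passed over all genes, against 9 and 6 at an unadjusted p under 0.05. In proteasome and muscle protein breakdown 1 of 36 rose, CAPN3, or 2 adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0404, and adjusted p = 0.749 with an estimated correlation). The immediate-early and heat-shock list had a median of -0.29 (camera adjusted p = 0.0417, and adjusted p = 0.454 with an estimated correlation), with 0 genes called by limma over all genes (5 at an unadjusted p under 0.05) and 4 lower adjusted over the list alone.

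The oxidative phosphorylation list had a median of -0.49 (camera adjusted p = 3.13e-07, and adjusted p = 0.581 with an estimated correlation) at this step, and the cytoplasmic ribosomal list one of -0.29 (camera adjusted p = 2.22e-07, and adjusted p = 0.598 with an estimated correlation). Over all genes and adjusted over the list alone, limma called 0 of the 53 oxidative genes and 1 of the 60 ribosomal ones, RPL3 (-1.02). At an unadjusted p under 0.05 there were 12 of the 53. On 60 days replicate 1 the oxidative list deviated from its stage mean by -0.624, the ribosomal list by -0.529 and the proteasome list by -0.506. Without that array the ribosomal median was -0.035 (adjusted p = 0.0708) and the oxidative one -0.18 (adjusted p = 0.00623). The proteasome list lay 0.662 above its stage mean on 60 days replicate 2, and without that array its median was -0.095 (adjusted p = 0.609). Calls of the other lists were lost without 3 days replicate 1 (proteasome and heat-shock), 3 days replicate 2 (proteasome), 3 days replicate 3 (slow-fibre, glycolysis, imprinted and heat-shock), 60 days replicate 2 (heat-shock), 60 days replicate 3 (slow-fibre, glycolysis, fatty acid, imprinted and interferon), and fetal replicate 1 or 3 (heat-shock), with adjusted p up to 0.192. The tricarboxylic acid cycle (-0.23), extracellular matrix (-0.20), erythroid (-0.47), immune (0.039), fast-fibre (-0.11), calcium handling (0.13), adipocyte (0.068), myogenic (-0.20), endothelial (-0.039), smooth muscle (-0.045), nerve (-0.12) and cartilage (-0.033) lists were not called. Members called in them were ME1 in the adipocyte list (higher), TFRC in the erythroid list, NEFL (-0.52) in the nerve list and SERPINH1 (-1.46) in the matrix list (all lower), each also adjusted over the list alone, where 1 myogenic gene was higher too. Median, mean and test differed in sign for the endothelial (-0.039, mean 0.016, test lower), smooth muscle (-0.045, mean -0.079, test higher) and cartilage (-0.033, mean 0.0021, test lower) lists.

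In total 247 probe sets passed between 3 and 60 days, 127 higher and 120 lower at 60 days, 147 of them at least 2-fold, with 2680 at an unadjusted p under 0.05 against 808 by chance. Arrays of the 2 stages did not overlap for 20.4% of probe sets, against 10% by chance. Centred on the hybridization controls, the split was 61 higher and 139 lower, and 8 of 37 named calls were lost. The proteasome, adipocyte and nerve lists then had 0 members called by limma in place of 1, while 3 fatty acid genes, 2 cell cycle genes and 1 heat-shock gene were lower and 1 interferon gene was higher. The count was 75 without 3 days replicate 1 and also without 3 days replicate 2, 91 without 60 days replicate 1, 151 without 120 days replicate 1 and 154 without 120 days replicate 2, and 39 when the 6 arrays of these stages were fitted alone.

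Some genes were highest at 3 days. A rise from the fetus to 3 days followed by a fall to 60 days was called for 81 probe sets, among them TFRC, ZNF385D, GLRX, TP53INP2, a regulator of autophagy, ACOT6, CPT1B, PPIF, the mitochondrial cyclophilin, and MCUR1, a regulator of the mitochondrial calcium uniporter. CPT1B averaged 83.0 ± 12.8, 695 ± 46.9, 241 ± 121 and 135 ± 22.9 (SD, n = 3) in stage order, and TFRC 40.8 ± 3.74, 557 ± 169, 70.2 ± 62.1 and 100.1 ± 82.5. The opposite course was called for 25 probe sets, among them NR3C1, the glucocorticoid receptor, with means of 405 ± 113, 120.4 ± 25.4 and 328 ± 27.5 up to 60 days, PDZRN3, a ubiquitin ligase of muscle, ZNF277, RBL2, a pocket protein of the retinoblastoma family, FAM69A, whose 1 other probe set was called higher at 3 days than in the fetus, ANKRD28 and STAMBPL1. The call from the fetus to 3 days held in 5 of 12 fits with 1 array left out for ANKRD28 (adjusted p up to 0.157, without 3 days replicate 3). For STAMBPL1 it held in 2 of 12 (up to 0.152, without fetal replicate 2). The call from 3 to 60 days held in all 12 such fits for ZNF385D and STAMBPL1. It held in 10 for TFRC and PDZRN3, 9 for GLRX, ACOT6 and CPT1B, and 8 for PPIF, MCUR1 and NR3C1. For TP53INP2 and RBL2 it held in 6, for ZNF277 and FAM69A in 4, and for ANKRD28 in 3. Both comparisons use the 3-day arrays. Independent lists of these sizes would share 24.4 probe sets for the peak and 28.8 for the trough, so the trough of 25 is not above that number. In 100 simulations with no change limma gave at most 0 and 1, but these made at most 3 calls at the first step and 1 at the second, so they do not show what overlap many real changes would give. Part of the excess of the peak may come from the shared arrays, since 3 arrays cannot be split into parts of 2 each. Falls at both steps were called for 14 probe sets (27.2 for independent lists) and rises at both for 27 (25.8). The peak count was 22 without 3 days replicate 1, 21 without 3 days replicate 2, 24 without 60 days replicate 1, 51 without 120 days replicate 1 and 53 without 120 days replicate 2, and the trough count 2, 7, 6, 8 and 10 in the same order, and 15 without 60 days replicate 2.

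**Figure D3:**
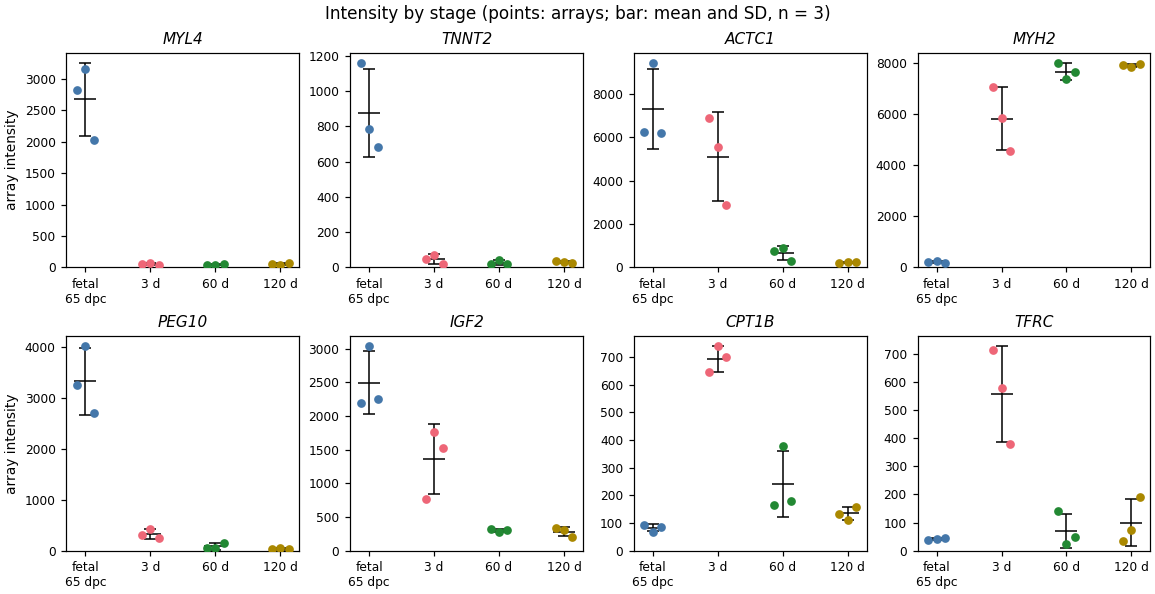
Array intensity (vertical axes, linear scale from 0) of 8 genes at the 4 stages (horizontal axes). Points are single arrays, and bars give the mean and SD of the 3 arrays of a stage. MYL4, TNNT2 and PEG10 are highest in the fetus, ACTC1 and IGF2 are high in the fetus and at 3 days, MYH2 is high at the 3 stages after birth, and CPT1B and TFRC are highest at 3 days.

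Between 60 and 120 days no probe set passed limma's test: 0 were called, with 1021 at an unadjusted p under 0.05 against 808 by chance, and a lowest adjusted p of 0.107. Arrays of the 2 stages did not overlap for 13.9% of probe sets, against 10% by chance. The lowest adjusted p belonged to FNTA, a subunit of farnesyltransferase, with 4511 ± 415 (SD, n = 3) at 60 days and 1930.2 ± 346 at 120 days, a log2 change of -1.23 ± 0.16 (SE). The changes of its 2 other probe sets, -0.27 and -0.03, did not pass. It passed with 1 probe set per gene (adjusted p = 0.0381), and it was chosen after its value was seen. Without 60 days replicate 3 there were 5 calls, 2 of them probe sets with no gene name, and the others EVL (1.06), UBA3 (-0.94) and a locus with no gene name (2.06), also chosen after their values were seen. MYH2 (0.045 ± 0.18), MYH7 (-0.11 ± 0.25), CKM (0.034 ± 0.18), IGF2 (-0.094 ± 0.29), MSTN (1.05 ± 0.59), TOP2A (0.22 ± 0.44), PDK4 (-0.86 ± 0.46), PPARGC1A (-1.46 ± 0.61), FABP4 (-0.28 ± 0.37) and ADIPOQ (-0.22 ± 0.53) did not pass. In simulated data with changes added at this step, the fit recovered 63% of 2-fold and 98% of 4-fold changes. The simulated noise was independent, with 1 spread per probe set for all stages. It therefore leaves out deviations shared by many probe sets of an array, and does not give the power with these arrays.

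Camera at the preset correlation called 7 lists between 60 and 120 days. By limma 0 of their members passed over all genes (from 0 to 4 per list did at an unadjusted p under 0.05). By fry, another list test, or with an estimated correlation, 0 lists were called. Oxidative phosphorylation had a median of 0.24 (camera adjusted p = 0.00654, and adjusted p = 0.872 with an estimated correlation), cytoplasmic ribosomal proteins 0.16 (camera adjusted p = 0.00187, and adjusted p = 0.872 with an estimated correlation), immune cells 0.30 (camera adjusted p = 0.0221, and adjusted p = 0.872 with an estimated correlation) and fast-fibre genes 0.17 (camera adjusted p = 0.0221, and adjusted p = 0.872 with an estimated correlation). Fatty acid uptake and oxidation had a median of -0.26 (camera adjusted p = 0.00187, and adjusted p = 0.702 with an estimated correlation), the tricarboxylic acid cycle -0.23 (camera adjusted p = 0.0221, and adjusted p = 0.872 with an estimated correlation) and immediate-early and heat-shock genes -0.15 (camera adjusted p = 0.0222, and adjusted p = 0.702 with an estimated correlation). Adjusted over the list alone, 1 heat-shock gene and 1 developmental isoform were lower, and no other list had a member called. Without 60 days replicate 1 the oxidative median turned to -0.087 (adjusted p = 0.362) and the ribosomal one to -0.096 (adjusted p = 4.34e-04). The medians of the other lists ran from -0.13 for imprinted genes (adjusted p = 0.129) to 0.20 for interferon response (adjusted p = 0.0593). Median, mean and test differed in sign for the developmental (0.12, mean -0.22, test lower), adipocyte (0.012, mean -0.043, test higher), erythroid (-0.017, mean 0.13, test higher), proteasome (0.0017, mean -0.076, test lower), endothelial (-0.02, mean -0.037, test higher) and cartilage (0.01, mean -0.047, test higher) lists. Single arrays also ended calls: 60 days replicate 1 (tricarboxylic acid cycle, oxidative phosphorylation and immune), 60 days replicate 2 (fast-fibre and immune), 60 days replicate 3 and 120 days replicate 1 (tricarboxylic acid cycle and heat-shock), 120 days replicate 2 (tricarboxylic acid cycle) and 120 days replicate 3 (oxidative phosphorylation, heat-shock and immune), with adjusted p up to 0.498.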

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

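The refits with other splits of the arrays were chosen before the results were seen, and the tests of the patterns in single arrays, in the ribosomal and oxidative lists and in the actin ratio after. Among 100 random splits of the 12 arrays into 4 groups of 3, 1 gave as many calls over all stages, the real one with 7588. The highest other gave 5526 and was the 1 split of 99 that kept the 3 fetal arrays together, while the rest gave at most 1. For the transient peak 1 of 100 splits, the real one, gave as many as 81, with a highest other of 0, and for the transient trough 1 of 100 gave as many as 25, with a highest other of 0. For the count over all stages chance can be excluded as the whole cause. The splits decide nothing about the transient counts, since those that mixed fetal with later arrays made at most 1 call over all stages, too few to share any between the steps. Independent lists would share 24.4 probe sets for the peak and 28.8 for the trough.

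The 6 arrays of a pair of stages can be split in 10 ways, too few for a share under 0.05. Between the fetus and 3 days 1 split, the real one, gave as many as 6945 calls, with a highest other of 0. Between 3 and 60 days 1 split gave as many as 247, with a highest other of 1, and between 3 and 120 days 1 gave as many as 714, with a highest other of 0. Between 60 and 120 days the real split gave 0 calls and the highest other 1. Any split gives at least 0, so the number of splits that reach the real count decides nothing there. For gene lists, 4 splits called as many as the real 12 between the fetus and 3 days (highest other 12). Between 3 and 60 days 1 split called as many as the real 11 (highest other 7), and between 3 and 120 days 1 as many as 11 (highest other 8). Between 60 and 120 days 4 called as many as 7 (highest other 8). Between the fetus and 3 days and between 60 and 120 days, splits that mixed the stages thus called as many lists as the real one. The number of lists called by camera does not set the real stages apart there. A mixed split can keep part of a stage difference, so these counts are not a rate of false calls.

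Fetal replicate 2 and 60 days replicate 1 deviated together from their stage means across probe sets (r = 0.646, probe sets not being independent). The mean 3-prime over 5-prime ratio of the spiked transcripts was 1.84 on them against 2.09 to 2.62 on the other 10 arrays, and 1 of the 66 pairs of arrays, this one, had a ratio as low, so preparation of the labelled RNA may be behind it. More connective tissue in these samples stays open: the matrix list lay 0.364 and 0.369 above its stage means, against at most 0.23 on the others. The ribosomal list lay at -0.0973 and -0.529, against a lowest of -0.0908 and an SD of 0.123 on the other 10, which keeps that explanation open. The samples' animals were not tested as an explanation.

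The fall of the ribosomal protein list from 3 to 60 days may come from 60 days replicate 1 alone: without it the median was -0.0351 against -0.29 with it, and the adjusted p 0.0708, in a range of 5.02e-13 to 0.598 over all alternatives. The oxidative phosphorylation list kept a median of -0.176 without the array, with an adjusted p of 0.00623 in a range of 1.45e-10 to 0.581, which does not settle whether that array alone set it. A difference between the ages stays open for both.

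The actin 3-prime over 5-prime ratio lay above all 3 fetal arrays on 8 of 9 arrays after birth. RNA degradation or shorter labelled RNA after birth would raise the ratio of other transcripts too. Of the 3 GAPDH pairs 2 were higher on all arrays after birth and 1 was lower, the one near the highest intensities of the arrays. The EF1A ratio also lay above all 3 fetal arrays on 8 of 9 arrays after birth, and 3 days replicate 3 was the exception for actin and EF1A. Degradation and a change of actin transcripts with age therefore cannot be told apart here, and either could contribute.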

How the results depend on the processing

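Leaving out both deviating arrays and centring on the hybridization controls were chosen after seeing the data, as was the comparison of 120 with 3 days. Over the alternatives, 0 named genes with a call, in the main fit or in the alternative, changed direction. Changes of sign without a call in either were not counted. For named genes with a call, it was kept in 2669 of 2818 values between the fetus and 3 days, 667 of 924 between 3 and 60 days and 791 of 899 between 3 and 120 days. For lists the result was the same in 584, 570, 567 and 588 of 621 values, which include those of lists not called. The direction of the list test was reversed, with a call in the main fit or the alternative, in 1, 1, 5 and 0. Changes of sign of a list median were not counted here. Of the lists called, 1 of 12, 0 of 11, 0 of 7 and 0 of 11 held in every alternative, in the order 3 days against fetal, 60 against 3, 120 against 60 and 120 against 3 days. The call held in every alternative for 84 of 113 named genes at the first step, 3 of 37 at the second (ACOT7, ZNF385D and STAMBPL1) and 16 of 36 between 3 and 120 days.

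Counts are given in that order unless named. With a median pseudocount the trough count was 16. Without a filter 1 probe set was called between 60 and 120 days, and the trough count was 11. Quantile normalization gave 7 lists between 3 and 60 days. Array weights gave 926 calls between 3 and 60 days, 4756 between 3 and 120 days, a peak of 258, a trough of 135 and 4 lists between 60 and 120 days. With only the 6 arrays compared there were 39 calls between 3 and 60 days and 1525 between 3 and 120 days. One probe set per gene, which tests fewer, gave 2629 over all stages, then 2372, 86, 1 and 286, a peak of 32 and a trough of 6. At least 2-fold changes numbered 2545, 147 and 337 in the comparisons with calls. An estimated correlation left 1, 0, 0 and 0 lists, and fry called 15, 5, 0 and 5. At the first step fry called 4 lists that camera did not. The slow-fibre (adjusted p = 0.007) and adipocyte (9.54e-04) lists were higher, and the myogenic (0.0138) and cartilage (1.74e-04) lists lower. The proteasome list was not called by fry (adjusted p = 0.1095). With both deviating arrays left out there were 111 calls between 3 and 60 days, 1147 between 3 and 120 days, a peak of 23 and a trough of 7. Centring on the hybridization controls gave a trough of 11. The cause was not tested, except where fewer probe sets or arrays are part of the alternative.

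With 1 array left out, calls ranged from 6007 to 7813 over all stages, 5394 to 7194 between the fetus and 3 days, 75 to 297 between 3 and 60 days, 0 to 5 between 60 and 120 days and 188 to 862 between 3 and 120 days. The peak ranged from 21 to 93 and the trough from 2 to 28. Lists called ranged from 11 to 14, 6 to 13, 4 to 8 and 8 to 12. The 6 lists came without 60 days replicate 3 and the 4 without 120 days replicate 3. Between 3 and 120 days the count was 326 and 324 without 3 days replicates 1 and 2, and 188, 222 and 433 without 120 days replicates 1, 2 and 3.

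Some list medians changed sign when 1 array was left out, and the range over single arrays is given with each. The immune list between the fetus and 3 days ranged from -0.80 without fetal replicate 2 to 0.50 without fetal replicate 3. Between 60 and 120 days the oxidative list ranged from -0.087 without 60 days replicate 1 to 0.43 without 60 days replicate 3, and the ribosomal list from -0.096 without 60 days replicate 1 to 0.33 without 60 days replicate 2. Both deviating arrays left out gave the same -0.087 and -0.096. The proteasome list ranged from -0.095 without 60 days replicate 2 to 0.31 without 60 days replicate 1 between 3 and 60 days, and from -0.20 without 60 days replicate 1 to 0.38 without 60 days replicate 2 between 60 and 120 days.

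With the replicate number as a block there were 161 calls between 3 and 60 days, a peak of 45 and a trough of 14. Arrays of the same number had residual correlations from -0.424 to 0.297 (median 0.0898, against -0.0414 for different numbers), and 3 of 12 arrays correlated best with one of their own number, so the arrays were not taken as pairs. The labels do not say what the number marks and give no sex, and a difference in sex between the animals of a stage stays open. Probe sets near the highest intensities, about those of the GAPDH controls, were not tested for compression, and for dim ones the pseudocount of 21 limits the size of a change.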

Other observations

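The comparison of 120 with 3 days and the genes FBXO32 and AMY2 were chosen after their values were seen. At 120 days, 714 probe sets differed from 3 days by limma, 371 higher and 343 lower, with 3143 at an unadjusted p under 0.05 against 808 by chance, and the stages did not overlap for 31.7% of probe sets, against 10% by chance. Centred on the hybridization controls, with a median shift of -0.16, the split was 166 higher and 494 lower, and 3 of 36 named calls were lost. Then 5 heat-shock genes were lower in place of 3, 4 oxidative phosphorylation genes in place of 2 and 4 cell cycle genes in place of 0. The adipocyte list had 1 higher and 1 lower in place of 2 and 0. By limma 1 glycolysis gene was higher in place of 0, and 0 myogenic and proteasome genes in place of 1 each. The count was 326 and 324 without 3 days replicates 1 and 2, and 188, 222 and 433 without 120 days replicates 1, 2 and 3. Of 36 named calls, 16 held without any single array.

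MSS51 rose by 3.84 ± 0.50 (SE, n = 3 per stage, adjusted p = 0.00250) in limma's fit, OCA2 by 2.99, RSAD2, an interferon-induced gene, by 2.57 and ALDH1A1 by 2.07. ACTC1 changed by -4.33 ± 0.40 (adjusted p = 4.62e-04), CASQ2 by -4.11, ZNF385D by -3.05, DNAJA4 by -2.80, PEG10 by -2.57, CPT1B by -2.21 and ACADL by -1.45. By camera 11 lists were called, 3 higher and 8 lower, and 0 with an estimated correlation. In interferon response 2 of 23 genes rose, or 5 adjusted over the list alone (median 0.76, camera adjusted p = 2.15e-04, and adjusted p = 0.694 with an estimated correlation). In fatty acid uptake and oxidation 6 of 24 fell, or 10 adjusted over the list alone (median -0.56, camera adjusted p = 2.22e-05, and adjusted p = 0.131 with an estimated correlation). In heat-shock and immediate-early genes 3 of 21 fell, or 10 adjusted over the list alone (median -0.82, camera adjusted p = 4.93e-04, and adjusted p = 0.131 with an estimated correlation). In immune cells 1 of 22 rose, also adjusted over the list alone (median 0.39, camera adjusted p = 0.0207, and adjusted p = 0.775 with an estimated correlation), a call lost without 3 days replicate 1 (adjusted p = 0.0546) or 120 days replicate 3 (0.175). Glycolysis and glycogen was called higher, and the developmental, tricarboxylic acid cycle, oxidative phosphorylation, cell cycle, imprinted and ribosomal lists lower, with camera adjusted p from 4.93e-04 to 0.0158. Of these, single arrays ended the calls of the tricarboxylic acid cycle (3 days replicates 1 and 2, 120 days replicates 1 and 2), oxidative phosphorylation (3 days replicates 1 and 2, 120 days replicate 1) and ribosomal (120 days replicate 3) lists, with adjusted p up to 0.192.

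FBXO32, a ubiquitin ligase of muscle atrophy, was at 2378 on 3 days replicate 3 and 2488 on 60 days replicate 2, against 26.4 and 61.2 on the other 3-day arrays and 176 and 625 on the other 60-day arrays, with 815 on fetal replicate 3, and was not called at any step. Of 3 probe sets of AMY2, an amylase, the one with the highest mean, which stands for the gene, did not pass from 3 to 60 days (-0.08). The 2 others rose (2.99 and 2.87, limma adjusted p = 0.00223 and 0.00251). Their values were close on each array (2162 and 1890 on 60 days replicate 1), so they are not taken as 2 separate observations.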
